A study of Mus musculus with 6 samples.

How the data were processed

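The data were 6 Affymetrix arrays of RNA from mouse Treg, 3 from liver and 3 from spleen, each array 1 sample. Per the labels' protocols, Foxp3-GFP mice received IL-2/IL-2 antibody complex on 3 days in a row, followed by 3 days without it, Treg were isolated from both organs, and total RNA was labelled with biotin. The labels describe the isolation both as fluorescence-activated sorting and as magnetic sorting, and which of these gave the RNA is not settled here. The array is named Mouse Gene ST 2.0 in the protocol and Mouse Transcriptome Array 1.0 in the column headers of the deposited table. The genome build and the annotation release behind the gene symbols are not given in the sources used here, so no coordinates are printed.

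The deposited values are log2 signals, 1 per array and transcript cluster. They were made with RMA (background correction, quantile normalization of probes and summary per transcript cluster) in Affymetrix Expression Console, per the submitters' processing notes, which state no version. RMA compresses differences of dim genes, and folds of genes near the background are compressed most. The array medians over all rows were not equal (5.68 to 5.9), although RMA normalizes probes to one distribution. The annotated table and the value table of the series held identical numbers (largest difference 0), and the first was used.

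The table had 72688 rows, of which 186 were spike-in or other control rows, 32901 had no gene symbol, 87 had several and 39514 had 1. Rows with 1 symbol were kept, and for the 526 symbols with more than 1 row the row with the highest mean over all 6 arrays was taken, which gave 38854 genes. Symbols are those of the file. Of these, 30744 were current symbols and 1664 further ones synonyms in a RefSeq gene table of assembly GRCm38.p6, used for names, biotypes and the order of genes along chromosomes. Of 551 list genes 7 were not found. Igj stands for Jchain, Emr1 for Adgre1, Folr4 for Izumo1r, Tgtp2 for Tgtp1, Klra33 for Klra4, Siglec5 for Siglecf and 4632428N05Rik for Vsir, as the table pairs these names; members of the Klra, Tgtp and Hspa1 families have near-identical copies and their levels are uncertain.

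Liver was compared with spleen for each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate was used, since the labels give no batch or pairing. Intervals are 95% confidence intervals from the same model. With 3 arrays against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so calls rest on limma's pooling of spread across genes. Gene lists were fixed before the data were examined: 18 of cell states, 15 of cell types that a liver or spleen sample can hold and 1 of sex-linked control genes. Each was tested with camera (two-sided, preset correlation 0.01, all genes tested as background) with adjustment over the 34 lists, and again with the correlation estimated from the residuals and with fry. Members were counted as having risen or fallen over all genes tested and adjusted over the list alone.

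Genes were named by a rule fixed before the data were examined: a fixed set in any case, which included Foxp3, Il2ra, Ctla4, Ikzf2, Il12rb1, Il12rb2, Stat4, Tbx21, Ifng, Il10, Klrg1, Cxcr3, Cxcr6 and Ccr7; the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out members of the cell type lists, immunoglobulin and T cell receptor segments, predicted models, microRNA and small nucleolar RNA genes and multigene families reported only as groups; and up to 4 called members of each list with the largest absolute difference, or, for a cell type list with none, the member with the highest mean. As 8 genes were called, other list members are named as examples chosen after their values were seen.

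The procedure was tested on simulated arrays with the means and spreads of the 38854 genes and 200 changed genes, for the liver and spleen comparison. It recovered 8.96% of genes changed by 0.5 on the log2 scale, 74.6% of those changed by 1 and 97.6% of those changed by 2, with 3.81% of calls false over 5 simulations. Camera called none of 170 unshifted lists and recovered a list shifted upwards in 5 of 5 simulations. The added shift was larger than the median found for the IL-12 axis list. Simulated genes were independent of each other, whereas estimated correlations in the real lists ran from 0.12 to 0.83. The simulated arrays also lacked differences shared by many genes of an array, such as those that set spleen array 5 apart. These figures therefore do not show how often camera or limma calls falsely in the real data, nor what share of real changes limma recovers there.

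Alternatives fixed before the data were examined were leaving out dim genes (the lower 50% by mean, or a mean under log2 5), subtracting array medians, quantile normalization, cyclic loess, averaging rows of a symbol, eBayes with trend and robust, array weights, a plain equal-variance test per gene, treat with a minimum fold of 1.5, the series value table, all rows, and leaving out each array. Others were added after the data were seen: the sets of arrays that share levels of Ctse and Habp2 as a block, the background rows as a covariate, liver arrays 2 and 3 averaged, protein-coding genes alone, and the prior degrees of freedom exchanged between the deposited and the rescaled values. Control rows entered no test.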

Results

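Gene expression was measured on 6 arrays of regulatory T cells (Treg) from Foxp3-GFP reporter mice, 3 of liver Treg and 3 of spleen Treg. Treg are the CD4 T cells that restrain other immune responses and depend on the transcription factor Foxp3, which the reporter marks. All mice had received a complex of interleukin-2 and an antibody against it, which expands Treg in vivo, on 3 successive days and then a pause of 3 days. The labels number the liver arrays 2, 3 and 7 and the spleen arrays 4, 5 and 6, and say neither whether each array came from a separate animal nor whether any liver and spleen array shared one. The p-values therefore measure only the spread between these arrays, which may be technical. The series title names sclerosing cholangitis and IL-12 signalling, but no sample carries a disease label. The question that could be addressed was how liver Treg differed from spleen Treg after expansion. Values are log2 signals, and the number of arrays limits their precision. The median over all rows lay between 5.68 and 5.9 per array, with spleen array 5 the highest. The rows that measure background averaged 4.55 on that array and 4.09 to 4.34 on the other 5.

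The liver Treg samples held more mRNA for the IL-12 receptor chain Il12rb2, the NK receptor Klrc1, the chemokine Ccl5 and the protease inhibitor Ctla2b than spleen Treg, and less for the transcription factors Zbtb10 and Spic, the chemokine Cxcl2 and neuritin, Nrn1. Markers of NK and dendritic cells were higher in the same liver samples by camera with its preset correlation, with list medians of 0.68 and 0.47 (adjusted p = 0.17 with an estimated correlation and 0.26 by fry for each). Klrc1 is itself a member of the NK list. Liver array 7 kept 0.475 of the excess over spleen that liver arrays 2 and 3 had in Klrc1, 0.633 of that in Il12rb2, 0.679 of that in Ctla2b and 0.799 of that in Ccl5, on the linear scale. Il12rb2 encodes the signalling chain of the receptor through which IL-12 activates Stat4. It measured 7.79 ± 0.21 (SD, n = 3) in liver and 6.56 ± 0.33 (SD, n = 3) in spleen, a 2.35-fold rise (log2 difference 1.23, SE 0.17, limma adjusted p = 0.0473). Klrc1, which encodes an inhibitory receptor of NK cells and of some T cells, rose 2.96-fold (log2 difference 1.56, SE 0.17, adjusted p = 0.0305). Ctla2b rose 2.03-fold and Ccl5 rose 1.90-fold, with adjusted p-values of 0.0425 and 0.0497. Zbtb10 was 2.13-fold higher in spleen, Cxcl2 2.11-fold, Nrn1 1.93-fold and Spic 1.96-fold, with adjusted p-values of 0.0473, 0.0497, 0.0425 and 0.0425. Spic, known from red pulp macrophages of the spleen, was dim, at 4.32 ± 0.13 in liver and 5.29 ± 0.10 in spleen (SD, n = 3). Its liver level, 4.48, 4.23 and 4.26 on arrays 2, 3 and 7, lay close to the background rows of those arrays (4.25, 4.34 and 4.15). Its fold is therefore uncertain, since folds near the background are compressed. In each of these 8 genes the 3 liver arrays lay on one side of the 3 spleen arrays. Their transcript clusters were TC0600002423.mm.1 for Il12rb2, TC0600003244.mm.1 for Klrc1, TC1300002141.mm.1 for Ctla2b, TC1100003396.mm.1 for Ccl5, TC0300000054.mm.1 for Zbtb10, TC0500000850.mm.1 for Cxcl2, TC1000002647.mm.1 for Spic and TC1300001812.mm.1 for Nrn1.

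These 8 genes, 4 higher and 4 lower in liver, were the only ones of 38854 tested that passed limma at a Benjamini-Hochberg adjusted p of 0.05, and 5 of them differed by at least 2-fold. At an unadjusted p under 0.05 there were 1464 genes. The groups did not overlap in 6.19% of all genes, where chance gives 10% for 3 arrays against 3. No gene passed limma after the array medians were subtracted, after quantile normalization or after cyclic loess (1448, 2391 and 2429 genes at an unadjusted p under 0.05), and leaving out 1 array gave 15 genes (liver 2), 1 (liver 3), 33 (liver 7), 23 (spleen 4), 0 (spleen 5, with 2017 at an unadjusted p under 0.05) and 19 (spleen 6). Of the 8 genes, 8, 1 and 4 were among those called without liver array 2, 3 and 7. Without spleen array 4, 5 and 6 it was 7, 0 and 6 of them. The median absolute log2 difference of the 8 genes stayed between 0.984 and 1.07 across the rescalings and the fits with 1 array left out. The even split of directions did not hold in all of them. Without liver array 7, 32 called genes were higher and 1 lower in liver. Without spleen array 6, 5 were higher and 14 lower.

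**Figure D1:**
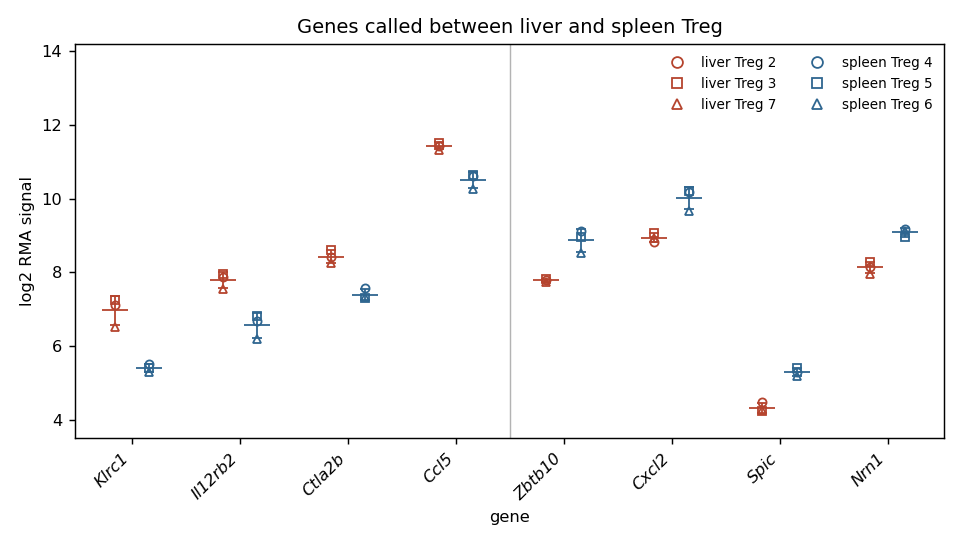
Log2 signal (vertical axis) of the 8 genes that passed the test (horizontal axis) on each array, liver Treg in red and spleen Treg in blue; horizontal bars are group means, error bars the SD of 3 arrays and symbols single arrays. The 4 genes left of the vertical line were higher in all 3 liver arrays, from Klrc1 at a log2 difference of 1.56 to Ccl5 at 0.92, and the 4 on the right were lower.

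Among the genes that define Treg, Foxp3 measured 9.47 ± 0.14 in liver and 9.49 ± 0.09 in spleen (SD, n = 3), with a difference of -0.02 and a 95% confidence interval from -0.28 to 0.23. The IL-2 receptor chain Il2ra differed by 0.03, the inhibitory receptor Ctla4 by 0.03 and the transcription factor Ikzf2 by -0.01. The signs of these 4 small differences were not stable between settings. Klrg1, a receptor of terminally differentiated Treg and cytotoxic cells, was high in both, at 11.8 and 11.7. Of the 21 members of the Treg identity list none passed, over all genes or adjusted over the list alone, and its median difference was -0.01 (camera adjusted p = 0.17). Fry called the list for change in either direction (adjusted p = 0.039). In 6 members all liver arrays lay below all spleen arrays and in 1 above, where chance gives 10% of genes in either direction. Camera called the list after cyclic loess (median -0.03, adjusted p = 0.012), without spleen array 5 (-0.00267, adjusted p = 0.0099) and without spleen array 6 (-0.07, adjusted p = 0.024). The members that differed most, chosen after their values were seen, were Bach2 at -0.41, Gpr83 at -0.39 and Satb1 at -0.35.

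Within the IL-12 and STAT4 / Th1 axis list, which holds the receptor, the signalling factors and the targets of the pathway in T helper 1 cells, 1 of 20 members rose (Il12rb2) and 19 did not pass. Adjusted over the list alone, 5 rose and 1 fell. Those 5 included Tbx21, the transcription factor that specifies Th1 cells, at a log2 difference of 0.45 (SE 0.11, limma adjusted p = 0.015 over the list alone) and the chemokine receptor Cxcr3 at 0.41 (adjusted p = 0.036 over the list alone). Ifngr2, a chain of the interferon gamma receptor, was the member that fell, at -0.45. The other receptor chain, Il12rb1, differed by 0.20 (95% confidence interval -0.04 to 0.44) and Stat4 by 0.12 (-0.14 to 0.38). With 1 array left out the Stat4 difference was 0.0459 to 0.19. Ifng, the main cytokine of Th1 cells, differed by 0.55 (SE 0.31), within the spread of the spleen arrays, of which array 6 was at 8.52 and the other 2 at 10.1 and 9.94. That difference was 0.0516 without spleen array 6 and 0.824 without spleen array 4. As a list these genes were higher in liver than other genes, with a median of 0.12 (camera adjusted p = 3.0e-06). The call was lost with an estimated correlation between genes (adjusted p = 0.59). The rotation test fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.54. Of the 20 members 7 belong to another list, and the NK cell and CD8 T cell lists were also higher by camera, with medians of 0.68 and 0.74 (adjusted p = 0.17 with an estimated correlation for each). The IL-12 axis median was 0.0629 without spleen array 6.

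**Figure D2:**
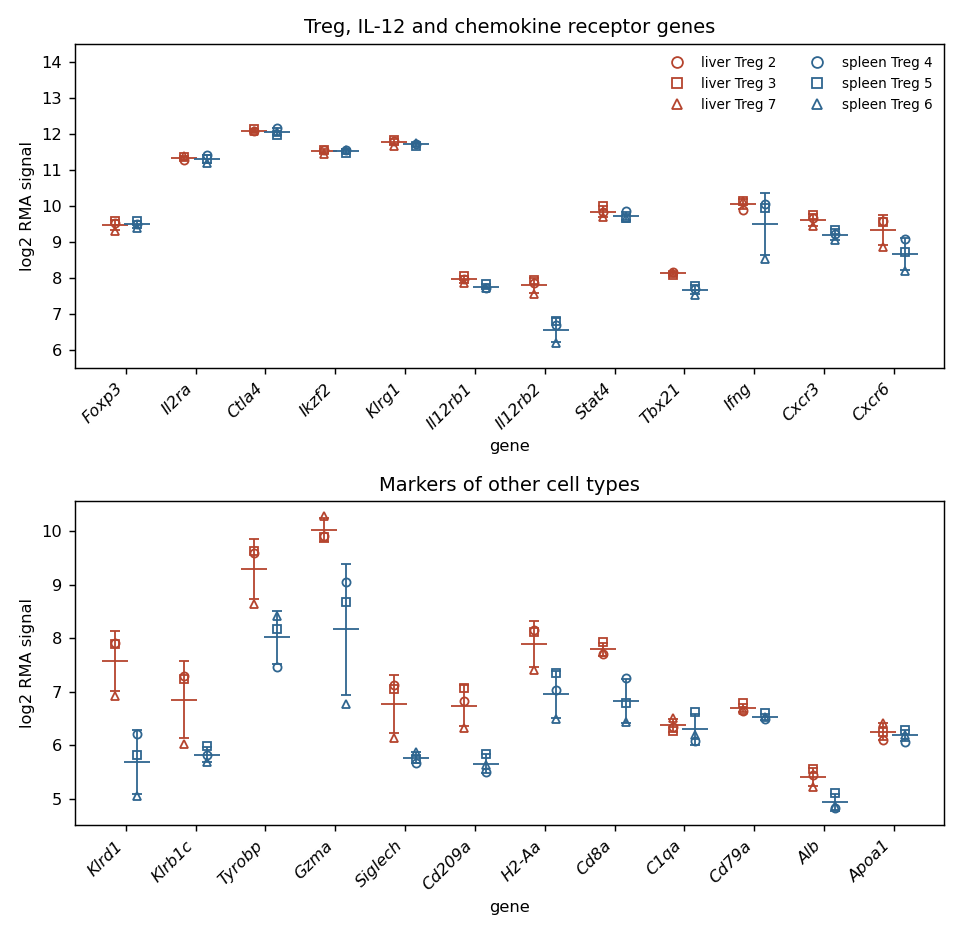
Log2 signal (vertical axis) of Treg, IL-12 axis and chemokine receptor genes (upper panel) and of markers of other cell types (lower panel) on each array, liver Treg in red and spleen Treg in blue; horizontal bars are group means, error bars the SD of 3 arrays and symbols single arrays. Foxp3, Il2ra, Ctla4, Ikzf2 and Klrg1 overlap between tissues while Il12rb2 does not, and in the lower panel liver arrays 2 and 3 lie above liver array 7 for Klrd1, Klrb1c, Tyrobp, Siglech, Cd209a and H2-Aa.

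By camera with its preset correlation the cell cycle list was higher in the liver samples, in which the NK cell, CD8 T cell and dendritic cell lists had medians of 0.68, 0.74 and 0.47 (adjusted p = 0.17 with an estimated correlation and 0.26 by fry for each of the 4 lists). None of the 36 members of the cell cycle list passed over all genes, and adjusted over the list alone 31 rose and none fell. The list's median difference was 0.46, or 1.38-fold, with 35 members positive (camera adjusted p = 1.2e-49, and 0.17 with an estimated correlation). It was 0.309 without spleen array 6 and 0.555 without spleen array 4. The members with the largest differences were the spindle checkpoint genes Bub1b at 0.70 and Bub1 at 0.65 and the ribonucleotide reductase subunit Rrm2 at 0.65. Interferon-induced genes went the same way in these samples. Of 22 interferon gamma response genes none passed over all genes and 11 rose adjusted over the list alone. Among them were the GTPase genes Iigp1 at 0.86 and Tgtp2 at 0.78, which has a near copy, Tgtp1, and is uncertain in its level for that reason. That list's median was 0.30 (camera adjusted p = 2.9e-22; adjusted p = 0.17 with an estimated correlation). Of 24 type I interferon response genes none passed over all genes and 7 rose adjusted over the list alone, led by Ifit3 at 0.79 and Ifit1 at 0.73. The list had a median of 0.21 (camera adjusted p = 8.7e-17; adjusted p = 0.32 with an estimated correlation) that was 0.097 without spleen array 6. Of 23 glycolysis and hypoxia genes none passed over all genes and 5 rose adjusted over the list alone, such as the enzyme genes Tpi1 at 0.74 and Pgk1 at 0.49. The list had a median of 0.16 (camera adjusted p = 9.3e-14; adjusted p = 0.33 with an estimated correlation) that was 0.0691 without spleen array 6 and 0.248 without spleen array 5. These examples were chosen after their values were seen, as were those named for the lists that follow.

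Ccr7, the receptor that guides T cells into lymphoid tissue, differed by -0.80 (SE 0.18, adjusted p = 0.33) and was the 1 member of the 19 in the central Treg and lymphoid homing list that fell adjusted over the list alone. None passed over all genes. Leaving out 1 array gave Ccr7 differences of -1.03 to -0.676, and in 1 of these 6 settings it passed over all genes (limma adjusted p = 0.033). The list's median was -0.17, lower in the liver samples by camera with its preset correlation (adjusted p = 8.8e-09). The call was lost with an estimated correlation (adjusted p = 0.46 with an estimated correlation), and fry gave an adjusted p of 0.33 against no change. Of 27 genes of tissue residency and chemokine receptors none passed over all genes, and adjusted over the list alone 6 rose and 1 fell. The collagen-binding integrin Itga1 was at 0.85 and Cxcr6, a receptor of liver-resident lymphocytes, at 0.66, while Cxcr4 was the member that fell, at -0.69. The groups overlapped in Cxcr6, with liver array 7 at 8.85 and spleen array 4 at 9.09, and its difference was 0.425 without spleen array 6. This list's median was 0.14 (camera adjusted p = 3.1e-06; adjusted p = 0.61 with an estimated correlation). Of its members 10 belong to another list, and the NK cell list moved the same way by camera, with a median of 0.68 (adjusted p = 0.17 with an estimated correlation). Without spleen array 5 the tissue residency list was not called (0.124, adjusted p = 0.081), and its median was 0.0934 with the arrays blocked by their levels of Ctse and Habp2. Of the 30 effector and tissue Treg genes none passed over all genes, and adjusted over the list alone 2 rose and 3 fell. The repair factor amphiregulin, Areg, was at -1.10 (SE 0.19, adjusted p = 0.14), and the inhibitory cytokine Il10 at -0.50 (SE 0.15, adjusted p = 0.58). Fgl2, a secreted suppressor product of Treg, was at 0.64. The median of that list was 0.06 (camera adjusted p = 0.17), and without spleen array 4 it was called (0.0925, adjusted p = 0.004).

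Among 29 cytokines made by T cells, Ccl5 rose and 28 did not pass. Adjusted over the list alone 3 rose and 2 fell, the 3 being Ccl5, Ccl4 at 0.69 and Ccl3 at 0.83 and the 2 being Areg and Il10. The list's median was 0.00 (camera adjusted p = 0.065). It was called without liver array 2 (0.0253, adjusted p = 0.035), liver array 3 (-0.00591, adjusted p = 0.041), spleen array 4 (-0.0118, adjusted p = 0.049) or spleen array 5 (0.0914, adjusted p = 0.033). It was also called without the lower 50% of genes by mean (0.113, adjusted p = 0.049), with the arrays blocked by their levels of Ctse and Habp2 (0.0104, adjusted p = 0.0029) and with liver arrays 2 and 3 averaged (0.0071, adjusted p = 0.032). Of 21 NF-kB and TNF family genes none passed over all genes and 5 fell adjusted over the list alone, including Tnfsf8 at -0.73 and Tnfsf11 at -0.51. The NF-kB list had a median of -0.12 (camera adjusted p = 5.1e-05; adjusted p = 0.66 with an estimated correlation). Without spleen array 4 that list was not called (-0.0953, adjusted p = 0.065), and its median was -0.0493 without spleen array 5, -0.203 without spleen array 6 and -0.0709 with the arrays blocked. Of 30 immediate early and dissociation genes none passed over all genes. Adjusted over the list alone 3 heat shock genes rose (Hspa1a, Hspa1b and Hsph1, the first 2 being near copies of each other and uncertain) and 4 genes fell, among them the nuclear receptors Nr4a2 at -0.60 and Nr4a3 at -0.50. This list, which also responds to the handling of tissue, had a median of -0.20 (camera adjusted p = 5.4e-05; adjusted p = 0.70 with an estimated correlation). It was not called without spleen array 4 (-0.117, adjusted p = 0.3) or with the arrays blocked by their levels of Ctse and Habp2 (-0.12, adjusted p = 0.062), and its median was -0.0673 without spleen array 5.

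Markers of NK cells, CD8 T cells and dendritic cells and the cytolytic genes were higher in the liver samples by camera with its preset correlation. None of these 4 lists was called for a shift in one direction by the other tests (adjusted p = 0.17 with an estimated correlation and 0.26 by fry for each). Of 16 NK cell and ILC1 genes Klrc1 rose and 15 did not pass. Adjusted over the list alone 10 rose and none fell. Klrd1, the partner chain of Klrc1, was at 1.88 (SE 0.29, adjusted p = 0.0695) and the adaptor gene Tyrobp at 1.27. The list's median was 0.68, or 1.60-fold (camera adjusted p = 3.0e-30; adjusted p = 0.17 with an estimated correlation), and 1.42 without the lower 50% of genes by mean. Of 8 CD8 T cell genes Klrc1 and Ccl5 rose and 6 did not pass. Adjusted over the list alone 5 rose, including Cd8a at 0.97. The CD8 list had a median of 0.74 (camera adjusted p = 1.3e-14; adjusted p = 0.17 with an estimated correlation), and 5 of its 8 genes belong to another list. Of 13 cytolytic genes none passed over all genes and 7 rose adjusted over the list alone, such as Gzma, which encodes a granzyme, at 1.86 (SE 0.42) and Klrk1 at 0.96. The cytolytic list had a median of 0.28 (camera adjusted p = 2.8e-13; adjusted p = 0.17 with an estimated correlation). Of 15 dendritic cell genes none passed over all genes and 9 rose adjusted over the list alone, including Cd209a at 1.08, Siglech, a marker of plasmacytoid dendritic cells, at 2.01-fold and the MHC class II gene H2-Ab1 at 0.95. The dendritic cell list had a median of 0.47 (camera adjusted p = 3.4e-19; adjusted p = 0.17 with an estimated correlation). Of the 19 NK and dendritic cell genes that passed adjusted over their list alone, 18 were higher in liver arrays 2 and 3 than in liver array 7. Klrb1c was at 7.29 and 7.24 there, at 6.03 in liver array 7 and at 5.68 to 5.98 in the spleen arrays. Gzma, in contrast, was at 9.90, 9.90 and 10.3 in liver arrays 2, 3 and 7. Foxp3 was also higher in liver arrays 2 and 3 than in array 7 (9.52 and 9.57 against 9.31), and Il2ra was not. The share of all genes with this order was not counted.

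Of the 24 hepatocyte genes none passed in either adjustment, and their median differed by 0.00 (camera adjusted p = 0.28). The list was called after cyclic loess (0.0249, adjusted p = 0.045) and without spleen array 5 (0.107, adjusted p = 0.0038). Albumin, Alb, among the most abundant mRNAs of liver tissue, measured 5.40 ± 0.17 in liver Treg and 4.93 ± 0.15 in spleen Treg (SD, n = 3), below the median gene of every array, with a difference of 0.47 (adjusted p = 0.48), and Apoa1 differed by 0.07. Ass1, an enzyme gene of the urea cycle with the highest mean of the list, was at 10.7 in both tissues and differed by 0.03. Of 16 macrophage and Kupffer cell genes none passed over all genes. Adjusted over the list alone Lyz2 at 1.39 and Mpeg1 at 1.15 rose and Hmox1 at -0.39 fell. Cd68, with the highest mean, differed by 0.23, and by 0.0641 to 0.422 with 1 array left out. The list's median was -0.04 (camera adjusted p = 0.17). The list was called without liver array 2 (0.00443, adjusted p = 0.019), with the arrays blocked (-0.0161, adjusted p = 0.031) and with liver arrays 2 and 3 averaged (-0.033, adjusted p = 0.029). Of 10 genes of splenic stroma and endothelium 1 fell adjusted over the list alone, Vcam1 at -0.53. Nkx2-5 differed by 0.07, and the splenic stroma median was -0.06 (camera adjusted p = 0.11), with a call without liver array 7 (-0.0987, adjusted p = 0.028) or spleen array 4 (-0.154, adjusted p = 0.017). Of 17 B cell and plasma cell genes none passed in either adjustment. Ighm differed by 0.16, and the median was 0.09 (camera adjusted p = 7.6e-05; adjusted p = 0.61 with an estimated correlation). That median was 0.00465 without spleen array 4, 0.156 without spleen array 5 and 0.148 without liver array 7, and the list was not called without the lower 50% of genes by mean (0.0675, adjusted p = 0.11). Of 8 gamma-delta and NKT cell genes 1 rose adjusted over the list alone, Tcrg-C2 at 0.98. That list had a median of 0.03 (camera adjusted p = 0.098) and a call without liver array 2 (0.0406, adjusted p = 0.033) or spleen array 5 (0.167, adjusted p = 0.0051). It was also called with the arrays blocked (0.0381, adjusted p = 0.026) and with liver arrays 2 and 3 averaged (0.011, adjusted p = 0.037). Tcrg-C2 passed over all genes with array weights and with the arrays blocked. The weights called 3533 genes in all, so a pass there is not particular to Tcrg-C2. Tbx21, Cxcr3, Cxcr6, Il12rb1 and Ifng each also passed in 1 of 16 alternatives, as did Ccr2, Ccr3, Ccr7, Cd68, Epor and Itgb3. Of these genes only Ccr7 passed with 1 array left out. Of 12 erythroid genes none passed in either adjustment. Epor differed by -0.15, and the median was -0.08 (camera adjusted p = 0.012; adjusted p = 0.64 with an estimated correlation). The erythroid call was lost without liver array 3 (-0.0743, adjusted p = 0.12) or spleen array 5 (-0.00102, adjusted p = 0.13) and after cyclic loess (-0.048, adjusted p = 0.056). It was also lost with the arrays blocked (-0.0554, adjusted p = 0.062) and with liver arrays 2 and 3 averaged (-0.0604, adjusted p = 0.053). The median was -0.0414 without liver array 2 and -0.149 without spleen array 4.

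The lists of the remaining cell types had medians within 0.07 of 0 and no member that passed in either adjustment. They were cholangiocytes (median 0.00, camera adjusted p = 0.63, Epcam at 0.01), sinusoidal endothelium (-0.02, adjusted p = 0.85, Pecam1 at -0.19), stellate cells and fibroblasts (-0.05, adjusted p = 0.15, Col1a1 at -0.07), neutrophils and monocytes (-0.03, adjusted p = 0.63, Ccr2 at 0.48), platelets and megakaryocytes (-0.06, adjusted p = 0.63, Itgb3 at 0.25) and mast cells, basophils and eosinophils (-0.04, adjusted p = 0.63, Ccr3 at 0.61). In the dendritic cell list the gene with the highest mean, Cd80, differed by 0.16, and by 0.0111 to 0.382 with 1 array left out. Medians were also within 0.07 of 0 for immune checkpoints (median 0.05, adjusted p = 0.66), Th2, Th17 and Tfh factors (-0.04, adjusted p = 0.63), fatty acid and cholesterol metabolism (0.01, adjusted p = 0.27), TGF-beta signalling (-0.05, adjusted p = 0.27) and survival and apoptosis (-0.01, adjusted p = 0.60), none of whose members passed in either adjustment. Calls appeared without spleen array 4 for stellate cells (-0.131, adjusted p = 0.012) and fatty acid metabolism (0.0813, adjusted p = 0.0065), without spleen array 6 for survival (-0.126, adjusted p = 0.041) and after cyclic loess for TGF-beta signalling (-0.0886, adjusted p = 0.0058). They also appeared with the arrays blocked for fatty acid metabolism (0.0604, adjusted p = 0.024) and without the lower 50% of genes by mean for neutrophils and monocytes (0.326, adjusted p = 0.0031). The sex-linked control genes had a median of -0.02 (adjusted p = 0.91), with no member that passed in either adjustment. For hepatocytes, sinusoidal endothelium, macrophages, neutrophils and mast cells the median was negative while camera's direction was upwards. The mean was positive for all of these but sinusoidal endothelium.

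**Figure D3:**
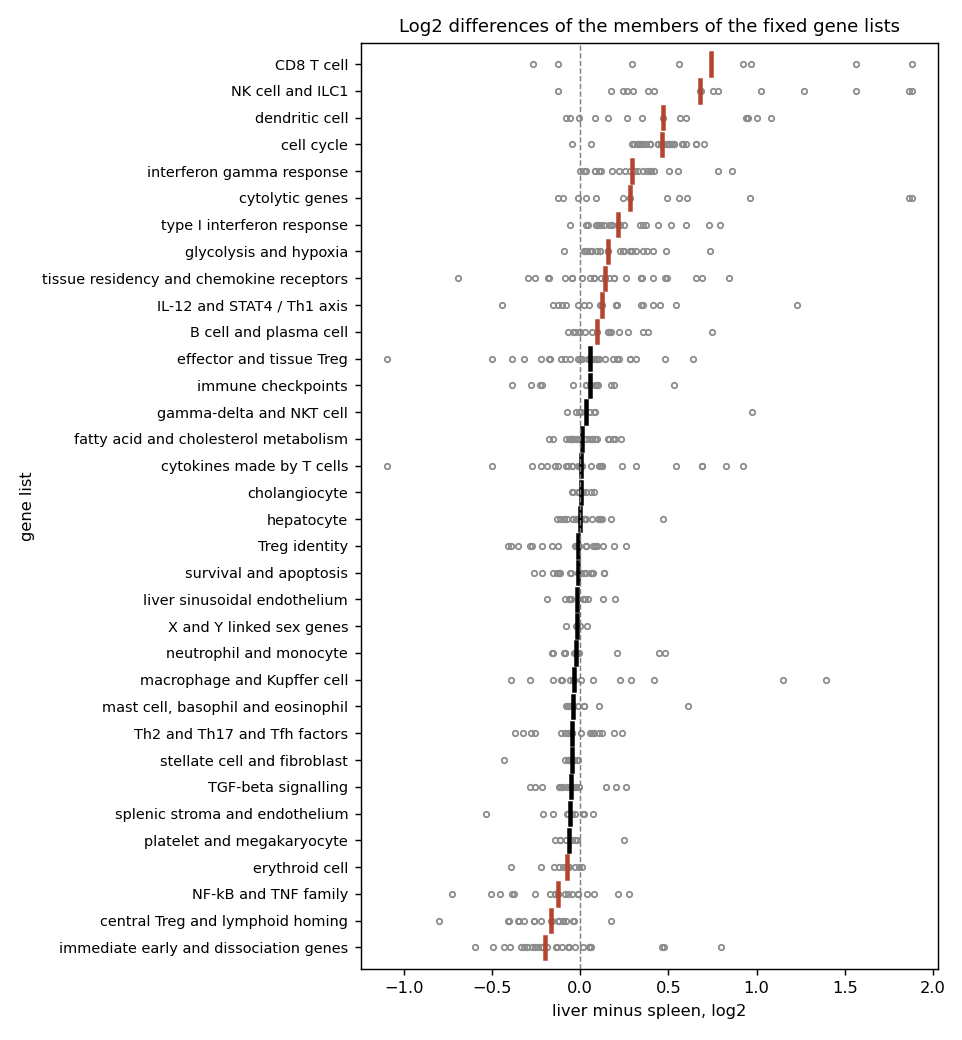
Liver minus spleen log2 difference (horizontal axis) of every measured member (circles) of the 34 fixed gene lists (vertical axis), with the median of each list as a bar, red where camera with a preset correlation called the list and black otherwise. The medians run from 0.74 for CD8 T cell genes to -0.20 for immediate early genes, and the 24 hepatocyte genes centre on 0.

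Of the 34 lists camera called 15, 11 higher and 4 lower in liver, and none was called when the correlation between genes was estimated from the residuals, where the lowest adjusted p was 0.17. The estimated correlations ran from 0.12 to 0.83. The rotation test fry called none for a shift in one direction (lowest adjusted p = 0.26) and 12 for change in either direction, which were the IL-12 axis, Treg identity, effector Treg, tissue residency, interferon gamma, NF-kB, cytolytic, cytokine, macrophage, dendritic cell, NK cell and CD8 T cell lists.

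Tissue was not the main axis along which the arrays differed. The first principal component held 38.6% of the variance and set spleen array 5, at a score of 42.8, apart from the other 5 at -17.7 to -2.38. In the second, with 28.2%, the tissues overlapped. The third, with 14.7%, had the liver arrays at -12.8 to -8.24 and the spleen arrays at 1.93 to 23.1. These separations were described without a test. Pearson correlations across genes were 0.9918 to 0.9974 for the 6 pairs of arrays from the same tissue and 0.9917 to 0.9957 for the 9 pairs from different tissues; genes are not independent replicates. Liver arrays 2 and 3 were the closest pair. Their log2 difference had an SD of 0.149, against 0.194 to 0.281 for the other 14 pairs. They were counted as 2 samples because the labels list them as 2, and whether they are a technical pair is not known. With the 2 averaged, added after the data were seen, 10 genes passed, 7 of them among the 8 named above. Ctse, which encodes the protease cathepsin E, and Habp2, which encodes a hyaluronan-binding protease, were chosen after their values were seen. Ctse was at 8.76, 8.67 and 8.74 on liver arrays 2 and 3 and spleen array 6 and at 11.2, 11.3 and 11.1 on liver array 7 and spleen arrays 4 and 5. Habp2 was at 8.37, 8.44 and 8.19 on the first 3 arrays and at 5.73, 5.51 and 5.66 on the others. With these sets of arrays as a block, added after the data were seen, 78 genes passed, 31 higher and 47 lower in liver, among them all 8 named above.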

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

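The block of arrays with shared Ctse and Habp2 levels, the background covariate, the averaging of liver arrays 2 and 3, the test of protein-coding genes alone, and the exchange of prior degrees of freedom were chosen after the data were seen. No paired analysis was possible because the labels do not say whether any liver and spleen array shared an animal. The counts of genes called, higher, lower and at least 2-fold (8, 4, 4 and 5) were the same with averaged rows and the series value table. They were 18, 14, 4 and 9 without the lower 50% of genes by mean; 21, 16, 5 and 10 without means under log2 5; 27, 19, 8 and 6 with trend and robust; 3533, 2377, 1156 and 102 with array weights, which gave liver array 2 a weight of 9.34 and spleen array 5 one of 0.188; 1, 0, 1 and 1 over all rows; 78, 31, 47 and 18 with the block; 10, 6, 4 and 7 with the pair averaged; and 166, 128, 38 and 19 over protein-coding genes. They were 0, 0, 0 and 0 with array medians subtracted, quantile normalization, cyclic loess, the background covariate and the plain test, with 1448, 2391, 2429, 2091 and 1090 genes at an unadjusted p under 0.05, and treat called 0 with 40. Leaving out 1 array gave 0 to 33 called, 0 to 32 higher, 0 to 14 lower and 0 to 30 at least 2-fold. With the prior degrees of freedom of the deposited values (8.2) the rescalings gave 18, 11, 7 and 8 (medians), 129, 81, 48 and 12 (quantile) and 137, 87, 50 and 11 (loess), each with all 8 genes. The deposited values with those after loess (3.1) gave 0, 0, 0 and 0, with 1117 at an unadjusted p under 0.05, so the fall in prior degrees of freedom ended these calls under the rescalings. The filters and the protein-coding test use fewer genes, which also changes the prior degrees of freedom (35 for protein-coding genes), and these effects were not separated. For the other moves the cause was not tested. The shift of the IL-12 axis list stayed positive and called under 13 of 15 alternatives (0.0629 to 0.181) and was not called with an estimated correlation (0.122, adjusted p = 0.59) or fry (0.122, adjusted p = 0.54). The other lists called numbered 14 to 17 in those 13 and 0 with an estimated correlation and with fry. Among uncalled lists, the median turned where a call appeared for hepatocyte genes with cyclic loess (0.0249) and without 1 array (-0.0492 to 0.107), neutrophil genes without the lower 50% (0.326), macrophage genes (-0.0807 to 0.0289) and T cell cytokines (-0.0118 to 0.0914) without 1 array. Of 559 values of named genes under alternatives, 469 kept direction and side of the threshold, 55 lost the call, 13 gained it and 22, uncalled before and after, changed sign. Most named genes were uncalled to begin with, and all 55 losses fell on the 8 called genes. Of 16 alternatives Klrc1 passed in 11, Il12rb2 and Ctla2b in 10, Zbtb10 in 9, Cxcl2 and Nrn1 in 8 and Ccl5 in 7. Spic passed in 9 of 15. The background rows at 4.09 to 4.55 limit what can be seen in dim genes such as Spic.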

Other observations

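The test of protein-coding genes and the tests below that weigh explanations, other than the splits for the list results, were chosen after the result they bear on was seen.

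When protein-coding genes alone were tested (19596 genes), limma called 166, of which 128 were higher and 38 lower in liver; 79 of the former and 31 of the latter belong to none of the fixed lists. The prior degrees of freedom, which measure how far limma pools the spread of genes, were 35 here and 8.2 over all genes. Among the 79 were the serpin genes Serpina3g at a log2 difference of 0.95 and Serpina3f at 0.85, near copies whose levels are uncertain, Alox5ap, which encodes a cofactor of leukotriene synthesis, 2.63-fold higher in liver, Rnase6 at 1.43, the helicase gene Hells at 0.74 and the primase gene Prim1 at 0.72. Among the 31 lower genes were the phosphatase gene Dusp10 at -0.76, the kinase gene Plk2 at -0.87 and Nsg2 at -0.77. These genes were chosen after their values were seen. Each had an adjusted p of 0.002 or less over protein-coding genes and of 0.0695 or more over all genes. Others of the 79 are of the same families as list members, such as the NK receptor genes Klrb1f at 0.90 and Klra17 at 1.11. The MHC class II gene H2-Eb1, at 0.53, is another. Belonging to none of the fixed lists therefore does not set a gene apart from the NK and dendritic cell patterns.

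When all 72502 rows that are not controls were tested, 1 passed, and it carries no gene symbol in the table. That row, TC0100001021.mm.1, was at 6.89 ± 0.04 in liver and 8.55 ± 0.10 in spleen (SD, n = 3), a log2 difference of -1.66 or 3.16-fold higher in spleen (limma adjusted p = 0.015). The immunoglobulin segment Igkv5-43 was at 6.94 and 6.44 in liver arrays 2 and 3, at 4.16 in liver array 7 and at 3.57 to 3.88 in the spleen arrays (adjusted p = 0.36).

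The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 8 genes and the highest of the other splits 6, so 1 of 10 splits gave as many. For genes higher and for genes lower in liver the real split gave 4 each and the highest other 5, and for genes with at least 2-fold both gave 5, so 2 of 10 splits gave as many in each case. For the IL-12 axis list the real median differed by 0.122 and the highest other by 0.152, and 3 of 10 splits gave as large a shift. Of the lists besides that one, the real split called 14 and the highest other 19, and 4 of 10 splits called as many.

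The 8 called genes lost their calls once array levels were equalised, which raises the question whether the brighter spleen array 5 made them. The smallest ratio of their log2 differences after cyclic loess to those before was 0.963. Cyclic loess moved the median liver minus spleen difference of all genes only from -0.018 to -0.0048. The 8 differences could thus hardly have shrunk, and their ratios cannot decide whether spleen array 5 made the calls. Their median SE was 0.137 before and 0.111 after, while the prior degrees of freedom fell from 8.2 to 3.1; held at 8.2, all 8 genes passed after cyclic loess, among 137, and with 3.1 in place of 8.2 none passed in the deposited values (limma, 1117 at an unadjusted p under 0.05). With spleen array 5 left out, the 8 log2 differences were 0.909 to 1.1 of those with it. This argues against that array as the source of these 8 differences. Their calls did depend on it, since 0 genes passed limma without it. The median SE was then 0.144 and the prior degrees of freedom 4.4, and what ended the calls there was not tested. The biological difference between liver and spleen Treg stays open as an explanation that was not tested.

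By camera with its preset correlation NK and dendritic cell markers were higher in the liver samples (adjusted p = 0.17 with an estimated correlation and 0.26 by fry for each list), and a candidate explanation is that such cells were among those sorted. A lower share of Treg that raised the markers of every other cell type alike was argued against by the difference of 0.708 between the median of 24 NK and dendritic cell genes (0.679) and that of 110 genes of other cell types (-0.0294; SD 0.223, quartiles -0.0707 and 0.0308), all with means of at least log2 5. The NK and dendritic cell lists were picked for their rise, the 110 genes leave out the CD8 T cell and the gamma-delta and NKT cell lists, of which the former had a median of 0.741, and among macrophage genes Lyz2 at 1.39 and Mpeg1 at 1.15 also rose adjusted over the list alone, so this excludes only a rise of every cell type alike. Of the 19 members that passed adjusted over their list alone, 18 were higher in liver arrays 2 and 3 than in array 7. Foxp3 had the same order (9.52 and 9.57 against 9.31) and Il2ra did not, and the share over all genes was not counted. Array 7 kept a median of 0.283 (quartiles 0.230 and 0.396) of the members' linear excess over spleen in liver arrays 2 and 3. For Il12rb2 it kept 0.633. Because this rests on 1 array, NK and dendritic cells in the sort cannot be told apart from expression by the Treg themselves. This holds for these members and for Il12rb2. Sorting for Foxp3-GFP selects against both cell types, but how far it removed them was not measured here, and the labels also name magnetic isolation. Of the 16 NK genes 5 belong to another list, and of the 15 dendritic cell genes 2 do. In spleen Treg 2 of the NK genes and 7 of the dendritic cell genes exceeded the median gene. The highest in liver were Gzma at 10.03, Tyrobp at 9.29 and Cd74 at 8.74.

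The levels of Ctse and Habp2 crossed the tissues, and the split they follow was the one that called 6 genes. Animals that differ in stretches of their genome are a candidate explanation: among the 20 genes with the smallest p in that split, 4 pairs lay within 50 genes of each other on a chromosome with 1 gene kept per family, against a median of 0 and a highest count of 6 in 10000 random sets counted in the same way (permutation p = 0.001), 0 for liver against spleen and 0 to 1 for the remaining 8 splits. The neighbours were Ctse, Nckap5 and Cd55, whose near copy Daf2 was not counted, on chromosome 1, Gdpd3 and Cln3 on chromosome 7, and Nnt, a gene known to be disrupted in the C57BL/6J strain, and D13Ertd608e on chromosome 13. A swap of liver array 7 with spleen array 6 was argued against, since of 188 list genes higher in liver arrays 2 and 3 than in spleen arrays 4 and 5, 168 were also higher in liver array 7 than in spleen array 6 (exact binomial p = 2.5e-30; genes are not independent). Nothing in the labels gives the animals' strain or litter, so this remains a hypothesis.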
